A study of Rattus norvegicus with 12 samples.

How the data were processed

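Messenger RNA of the duodenal mucosa was measured in 12 female Sprague-Dawley rats, an outbred laboratory strain, aged 9 weeks. Per the labels, rats were assigned at random to a swimming group and a sedentary control group that was kept in the pool for the same 2 weeks, at a water temperature of 30 to 32 °C. The swimming rats were trained for 1 week until they could swim without a break for 1 hour per day, and then swam on 5 days per week. Epithelial cells were scraped from a duodenal segment of 10 cm, and the total RNA was amplified to biotin-labelled cRNA and hybridised to single-colour Illumina bead arrays for the rat with 22523 probes, 1 array per sample. The groups were taken from the sample titles, 6 arrays each.

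The deposited raw table holds, per the file headers, the average signal of each probe, an intensity on a linear scale. It holds no value below 0, and the medians of the 12 arrays lay between 62.7 and 88.8, so these values were neither background-subtracted nor scaled between arrays. A second table deposited by the authors holds processed intensities of the same arrays. These are on a linear scale with 26.2 to 26.3% of values below 0 and the same median, 16.0, in every array, and each column ranks its probes as the raw column of the same array does. The scale is linear and the values are background-subtracted and scaled, but the method is not given in the sources used here, and neither is the reading software. The tables hold no detection p-values, so no probe was called present or absent. Signal near the bottom of the scale is described instead by whether a probe was dimmer than the median probe over the 12 arrays, and a difference between such probes understates a change in RNA.

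The raw intensities were background-corrected with normexp (offset 50), quantile-normalized between arrays and put on a log2 scale, with limma 3.58.1 in R 4.3.3. All 22523 probes were kept. Differences, swimming minus control, were tested with limma (lmFit and eBayes, two-sided) on all 12 arrays, and Benjamini-Hochberg adjustment ran over all probes, with calls at adjusted p under 0.05. Probe names came from the platform annotation, which is old, and were updated through the Entrez identifier with the gene table of rat assembly GRCr8. 13793 probes have 1 gene symbol, none has several and 8730 are unnamed here. 13752 probes matched by identifier, and no symbol changed. No genome build is named for the arrays, so no coordinates are given. Where a gene has several probes, the probe with the highest mean over the 12 arrays stands for it.

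Gene lists of 22 functions and 17 cell types were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the 39 lists), with camera at an estimated correlation and fry as alternatives. 28 genes stand in more than 1 list. The mean of the calcium absorption list and of the tight junction list in each rat was compared with an exact permutation test, two-sided, over all 924 assignments of the arrays, of which the smallest possible p is 0.00216. A single list at that p would not pass adjustment over 39 lists, so adjusted exact p-values of list means say little. Named genes followed a rule. It takes the 10 probes with the smallest unadjusted p when fewer than 10 pass the threshold, provided they have 1 symbol that is not a predicted locus and are brighter than the median probe. It also takes every measured member of the calcium absorption list, and from each list up to 4 members with the smallest p. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The 3 settings that average or leave out particular arrays, the permutation test of every list mean and the segment markers were chosen after seeing the data.

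Every pair of arrays was compared by the spread (scaled median absolute deviation) of log2 differences over 4933 bright probes (mean above 8) and over 5147 dim probes (mean under 6.1), where only technical noise is expected. In 3 pairs the bright spread was below the dim spread. 2 of these pairs lie within a group and were averaged to 1 sample each for the mean ± SD of each group, which therefore has n = 5. The means ± SD of segment markers over the arrays other than swimming 5 count each of the 11 arrays singly. Fold changes, SE and p come from all 12 arrays, with near-identical arrays counted as separate. They therefore differ from the difference of the printed means, and SE and p rest on more arrays than the n = 5 of those means. For Pck1 the printed means are 11.12 and 12.42 and the fitted difference is 1.46. A restricted comparison, of 4 control samples with 3 swimming samples, leaves out the array labelled swimming 5 and both arrays of the third pair, which spans the groups. Its exact permutation test has 35 assignments and a smallest possible p of 0.0286, so its exact p-values are coarse.

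The tests were tried on simulated data with the measured probe variances, in which 200 of the 22523 probes were changed. All 200 were drawn from the probes brighter than the median, so the rates of calls below do not cover dimmer probes. limma called 35.8% of the probes changed by 0.5 log2, 76.1% of those changed by 1 and 93.9% of those changed by 2, with 5 false calls, and the list tests recovered 2 of 2 shifted lists with 0 others. The noise was drawn independently for each probe and array, without correlation between genes and without near-identical arrays. These rates may therefore not hold for the real comparison. They cannot show how often camera with the preset correlation calls unshifted lists in these data. Alternatives covered the background correction, the scaling between arrays, the authors' processed intensities on a log2 scale (floor 16), dim probes, the variance model, array weights, the replicate number as a block, the choice of probes and members, the set test, and leaving out each array. The floor lies just below the median of the authors' values in each array (16.0). Nearly all values below that median were therefore set to the same level, so dim probes could hardly differ in that setting. Beadchip positions were not used here, since the files carry none. The number of arrays limits the precision. The median 95% confidence interval of a probe brighter than the median reached 0.28 log2 to either side. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.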

Results

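Gene expression in the duodenal mucosa was compared between rats that swam for 1 hour per day over 2 weeks and sedentary rats kept in the pool. Of the 12 arrays, 6 came from each group, and their raw median intensities lay between 62.7 and 88.8. The study asked how the duodenal epithelium responds to endurance swimming, and the duodenum is a site of active calcium absorption.

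The array labelled swimming 5 carried a different set of intestinal segment genes from the other 11. Of 19 measured markers of the proximal small intestine, 15 lay below every other array by more than 1 log2. Alpi, the intestinal alkaline phosphatase of the brush border, read 5.998 against 14.86 ± 0.11 in the other arrays (SD, n = 11), and Gata4, a transcription factor of the proximal small intestine, read 5.69 against 10.57 ± 0.15. Of 13 markers of the large intestine, 7 lay above every other array by more than 1 log2, among them Car1, a carbonic anhydrase of the colon, at 14.94 against 7.33 ± 0.61, and Hoxa7, a positional gene, at 10.76 against 5.92 ± 0.17. The markers were listed after this array had been seen to stand apart. Values without this array stand beside many of the results below.

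**Figure D1:**
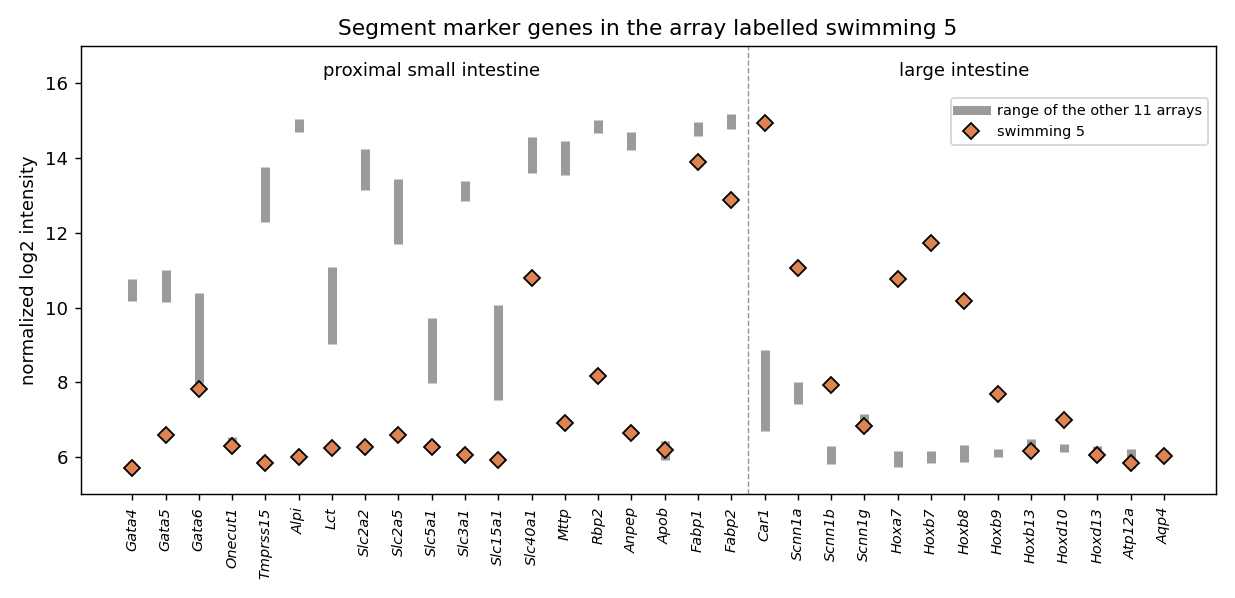
Normalized log2 intensity of marker genes of the proximal small intestine (left) and the large intestine (right). Grey bars span the other 11 arrays and diamonds mark the array labelled swimming 5, which lies below all others by more than 1 log2 for 15 of 19 proximal markers and above them for 7 of 13 large intestine markers.

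Arrays of 3 pairs were nearly identical. The spread of bright probes was 0.078 log2 between control 3 and swimming 3, 0.12 between control 4 and control 6, and 0.16 between swimming 4 and swimming 6, while it was at least 0.22 in the 52 other pairs that leave out swimming 5. At most 1 of 4933 bright probes differed by more than 1 log2 within these pairs, against at least 51 in the others. Each of the 2 pairs within a group differed by less than the noise of dim probes and was counted as 1 sample in means and SD. The pair of control 3 and swimming 3 spans the comparison, so it contributes almost the same profile to both groups.

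**Figure D2:**
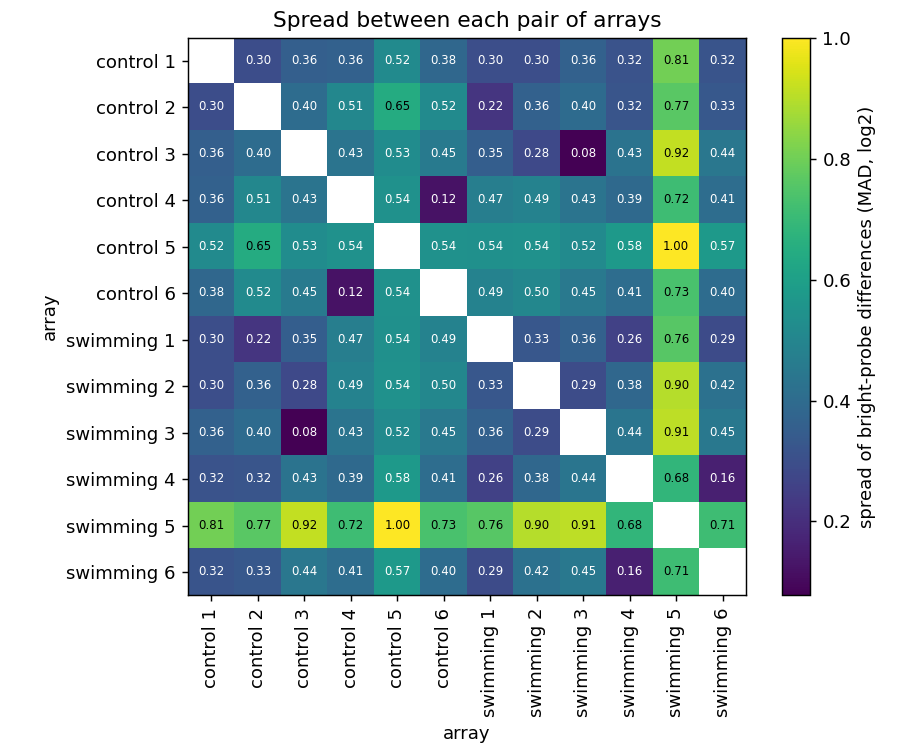
Spread of log2 differences over bright probes between each pair of the 12 arrays, as a scaled median absolute deviation (colour and printed values). The lowest values are those of control 3 with swimming 3 (0.078), control 4 with control 6 (0.12) and swimming 4 with swimming 6 (0.16), and the highest are in the row of swimming 5.

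No gene passed the test between swimming and control rats after adjustment, so the genes below are named as not passing. Among those with the smallest p, Pck1, the cytosolic enzyme that opens gluconeogenesis, had a mean log2 intensity of 11.12 ± 0.92 in control and 12.42 ± 0.31 in swimming rats (SD, n = 5 each), a fitted difference of 1.46 (SE 0.36). Aqp1, a water channel of endothelium and other cells, read 8.77 ± 0.45 in control and 9.97 ± 0.52 in swimming rats, a difference of 1.25 (SE 0.24). Lypd3 differed by -0.61 (SE 0.12) and Nr0b2, the bile acid-induced repressor SHP, by -0.60 (SE 0.14). The other members of this group also read lower in swimming rats. The differences were -0.52 for Ackr3, a scavenger receptor of the chemokine CXCL12, -0.46 for Dcun1d4, -0.42 for Ypel2, -0.42 for Akr1c2, -0.37 for Deaf1 and -0.28 for Taldo1, transaldolase of the pentose phosphate pathway. In all 10 genes the adjusted p from limma was 0.911. Of the 10, 2 were higher and 8 lower in swimming rats. In each, 6 of 6 swimming arrays lay on the same side of the control mean, which the choice by smallest p favours. Counts of swimming arrays, here and below, take both arrays of the near-identical swimming pair as separate. They also include swimming 5 and the swimming array that is near-identical to a control array. Such counts may therefore rest on fewer than 6 independent duodenal samples.

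limma called 0 of 22523 probes, with 1076 at an unadjusted p under 0.05 where chance alone gives 1126. It also called 0 without swimming 5 (1137 unadjusted) and 0 in the restricted comparison (737 unadjusted), and no alternative tried gave a call. The smallest adjusted p was 0.911 with all arrays, 0.112 without control 3 and 0.205 without swimming 3, the arrays of the near-identical pair that spans the groups. It was 0.993 in the restricted comparison, which leaves out both arrays of that pair. With the pairs within groups averaged it was 0.986, and without control 2 it was 0.622.

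Genes of transcellular calcium absorption, the route by which enterocytes carry calcium across the cell, did not pass as a group. Of 18 measured members 7 read higher and 11 lower in swimming rats, and 0 passed either over all probes or adjusted over the list alone. S100g, the cytosolic calcium carrier calbindin-D9k, read 14.92 ± 0.12 in control and 14.73 ± 0.11 in swimming rats (SD, n = 5 each), a difference of -0.25 (SE 0.077) and on the same side in 6 of 6 swimming arrays. Trpv6, the apical calcium channel, read 9.75 ± 0.45 and 9.39 ± 0.45, a difference of -0.45 (SE 0.24; -0.54 without swimming 5). Atp2b1, the basolateral calcium pump PMCA1, differed by -0.34 (SE 0.36; -0.21 without swimming 5), and Vdr, the vitamin D receptor, by 0.028 (SE 0.11; 0.11 without swimming 5). For Atp2b1 control 5 read 13.84, against 12.00 to 13.05 in the other controls. Pdia3, an endoplasmic reticulum protein that is also a membrane binding site for vitamin D, read 11.69 ± 0.45 and 12.06 ± 0.12, a difference of 0.47 (SE 0.19). Atp2a3, a calcium pump of the endoplasmic reticulum, differed by 0.68 (SE 0.38) with all arrays and by 0.29 without swimming 5, and its relative Atp2a2 by 0.25 (SE 0.18). Cyp24a1, the vitamin D-degrading enzyme, differed by 0.18 (SE 0.25) with all arrays and by -0.069 without swimming 5. Prlr, the prolactin receptor, differed by -0.14 (SE 0.33) with all arrays, by 0.18 without swimming 5 and by 0.037 under median scaling. Rxra and Casr lay between -0.13 and -0.031, and Trpv5, Calb1, Atp2b2, Atp2b4, Slc8a1, Cacna1d and Pth1r were dimmer than the median probe, where differences lay between -0.13 and 0.044. The adjusted p from limma was 0.911 for S100g, Trpv6 and Pdia3.

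**Figure D3:**
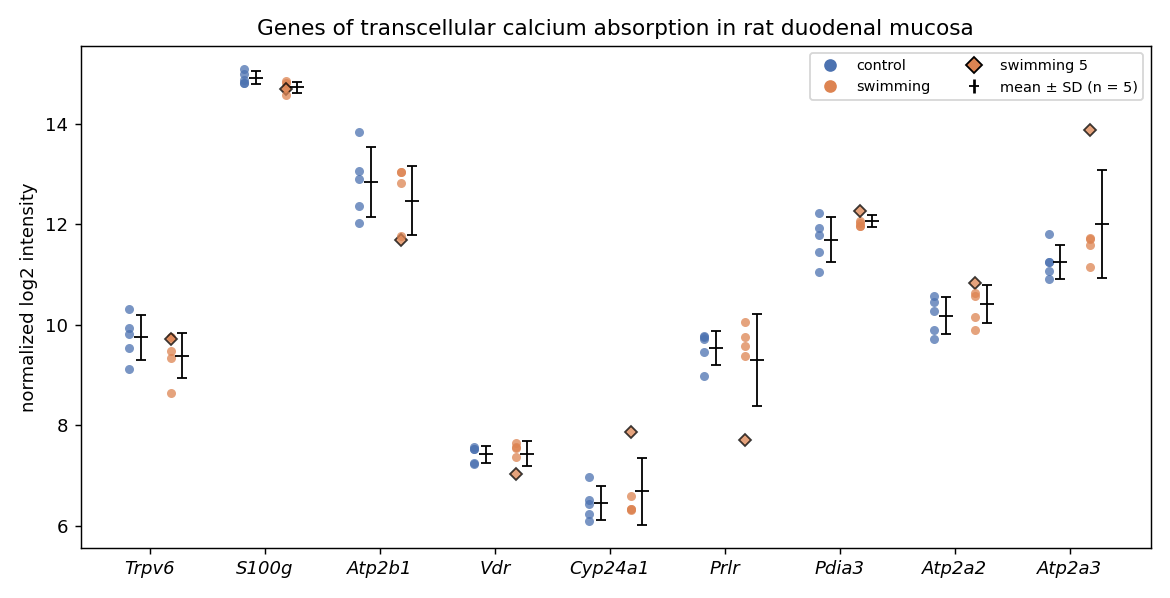
Normalized log2 intensity of 9 genes of transcellular calcium absorption that were brighter than other members of the list or named for their role. Points are samples (n = 5 per group after averaging near-identical arrays), bars give the mean ± SD, and the diamond is swimming 5, which lies apart in Atp2a3, Cyp24a1 and Prlr. S100g read 14.92 ± 0.12 in control and 14.73 ± 0.11 in swimming rats.

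The mean of the calcium list per rat differed by -0.00015 log2 between groups (exact permutation test, two-sided, p = 0.998). Its sign turned under median scaling (0.044), cyclic loess (0.0050) and when near-identical pairs were averaged (0.0065; exact permutation p = 0.897), with no exact p under 0.05. The 12-array test counts near-identical arrays as separate. The median over members in each rat differed by -0.051 (exact permutation p = 0.584). Members that read higher and lower offset each other in a list mean. A mean near 0 therefore does not show that each calcium gene was unchanged. Tight junction genes, which seal the paracellular route, differed by 0.035 as a list (exact permutation test, two-sided, p = 0.316), by 0.012 without swimming 5 and by -0.00028 in the restricted comparison. Of 31 measured, 19 read higher and 0 passed over all probes or adjusted over the list alone. Cldn3 differed by 0.29 (SE 0.13; 0.18 without swimming 5), Cldn5 by 0.21 (SE 0.094) and Marveld2, the tricellular junction protein tricellulin, by -0.23 (SE 0.089).

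Ribosomal protein genes read higher as a group in swimming rats. Of 61 measured, 55 lay above their control mean, by 0.18 on average, and the list mean was higher in 5 of 6 swimming arrays. Rpl23a differed by 0.23, Rpl7 by 0.58 and Rpl18 by 0.21. Camera with its preset correlation gave adjusted p = 8.04e-09, but camera gave adjusted p = 0.599 with an estimated correlation. Cell cycle and DNA replication genes were also higher as a list, 37 of 43 of them, by 0.17 on average and in 4 of 6 swimming arrays, with Gins1 at 0.33, Ttk at 0.28 and Cdc6 at 0.25. Their adjusted p was 0.000432 with the preset correlation, and the adjusted p was 0.708 with an estimated correlation. The cell cycle mean was 0.093 without control 5 (adjusted p = 0.0896) and 0.083 with near-identical pairs averaged and swimming 5 left out (adjusted p = 0.118). With the preset correlation the cell cycle list stayed called without swimming 5 (0.12, adjusted p = 0.00770) and in the restricted comparison (0.14, adjusted p = 0.00637). The 5 arrays with the highest means of the ribosomal list, swimming 1, 4, 5 and 6 and control 2, were also the 5 highest for the cell cycle list and for crypt stem and transit cell markers, which averaged 0.20 higher in swimming rats without being called. In neither list did any member pass over all probes or adjusted over the list alone.

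Interferon response genes read lower as a group. Of 39 measured, 32 lay below their control mean, by 0.16 on average, and the list mean was lower in 6 of 6 swimming arrays. Without swimming 5 the mean was -0.091. The differences were -0.31 (SE 0.10) for Adar, an RNA-editing enzyme, and -0.82 (SE 0.34) for Tap2, the peptide transporter of antigen presentation. Gbp5, a dim probe, differed by -0.14, while Cxcl11 differed by 0.48. Camera gave adjusted p = 0.000432 with the preset correlation and adjusted p = 0.454 with an estimated correlation. Cholesterol biosynthesis genes were lower in 14 of 16 cases, by 0.23 on average and in 4 of 6 swimming arrays, with Mvd at -0.87 (SE 0.24), Cyp51 at -0.44 and Sc5d at -0.43 (-0.28 without swimming 5). The adjusted p was 0.00691, and the adjusted p was 0.599 with an estimated correlation. Their mean was -0.12 without swimming 5 (adjusted p = 0.133), -0.17 without control 1 (adjusted p = 0.152) and -0.10 under median scaling (adjusted p = 0.321). In the restricted comparison it was -0.091 (adjusted p = 0.406). Oxidative phosphorylation genes were lower in 38 of 56 cases, by 0.051 on average and in 3 of 6 swimming arrays, with Atp5pd at -0.26, Uqcrc1 at -0.28 and Atp5me at -0.17. The adjusted p was 0.0492, and the adjusted p was 0.708 with an estimated correlation. Their mean was -0.016 without swimming 5 (adjusted p = 0.4995) and turned to 0.013 under median scaling. It was -0.0046 in the restricted comparison (adjusted p = 0.745), -0.020 without control 1 (adjusted p = 0.389) and -0.029 without control 2 (0.235), and leaving out control 3, swimming 4 or swimming 6 gave adjusted p of 0.101, 0.0981 and 0.127. With the preset correlation the call was also lost with no background correction (adjusted p = 0.0530), offset 16 (0.0729) and eBayes trend and robust (0.0777). Under cyclic loess the mean was -0.033 (adjusted p = 0.196). With all arrays no member of these 3 lists passed over all probes or adjusted over the list alone. Without swimming 5, Pmvk, a kinase of the mevalonate pathway, passed when adjusted over the cholesterol list alone, at -0.39 (-0.25 with all arrays).

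Among markers of cells and tissues beside the epithelium, camera called 3 lists with its preset correlation. Red blood cell genes were lower in 8 of 9 cases, by 0.41 on average, and the list mean was lower in 6 of 6 swimming arrays. The globin genes Hbb, Hbb-b1 and Hba-a1 differed by -1.22 (SE 0.37), -1.09 (SE 0.32) and -0.99 (SE 0.38), or -0.93, -0.86 and -0.62 without swimming 5, and Hbb and Hbb-b1 passed when adjusted over the list alone, as did all 3 without swimming 5. Camera gave adjusted p = 0.00162 with the preset correlation and adjusted p = 0.454 with an estimated correlation. Fibroblast and stroma genes were higher in 17 of 20 cases, by 0.20 on average and in 6 of 6 swimming arrays, with the collagen genes Col1a2 at 0.75, Col1a1 at 0.32 and Col6a2 at 0.16. The adjusted p was 0.00162, and the adjusted p was 0.599 with an estimated correlation. Without swimming 1 the stroma mean was 0.13 and its adjusted p 0.0803. Control 2 and swimming 1 had the highest stroma means (7.78 and 7.80). They were also the highest for smooth muscle (7.69 and 7.69) and endothelial cell genes (6.86 and 6.92). Digestive enzymes of the exocrine pancreas, a gland beside the duodenum, were higher in 22 of 22 cases, by 0.64 on average and in 3 of 6 swimming arrays, with Cel at 0.78 and Cela1 at 0.41. The adjusted p was 0.000777, and the adjusted p was 0.708 with an estimated correlation. This list rested on single arrays. It averaged 9.71 in swimming 2, 8.82 in control 3, 8.81 in swimming 3 and 7.35 in swimming 1, and between 6.42 and 6.71 in the other 8 arrays. Without swimming 2 its difference was 0.21, with adjusted p = 0.176. It was 0.86 without swimming 5 and 1.30 in the restricted comparison (adjusted p = 9.35e-11, and adjusted p = 0.662 with an estimated correlation). No member of the stroma and pancreas lists passed over all probes or adjusted over the list alone.

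**Figure D4:**
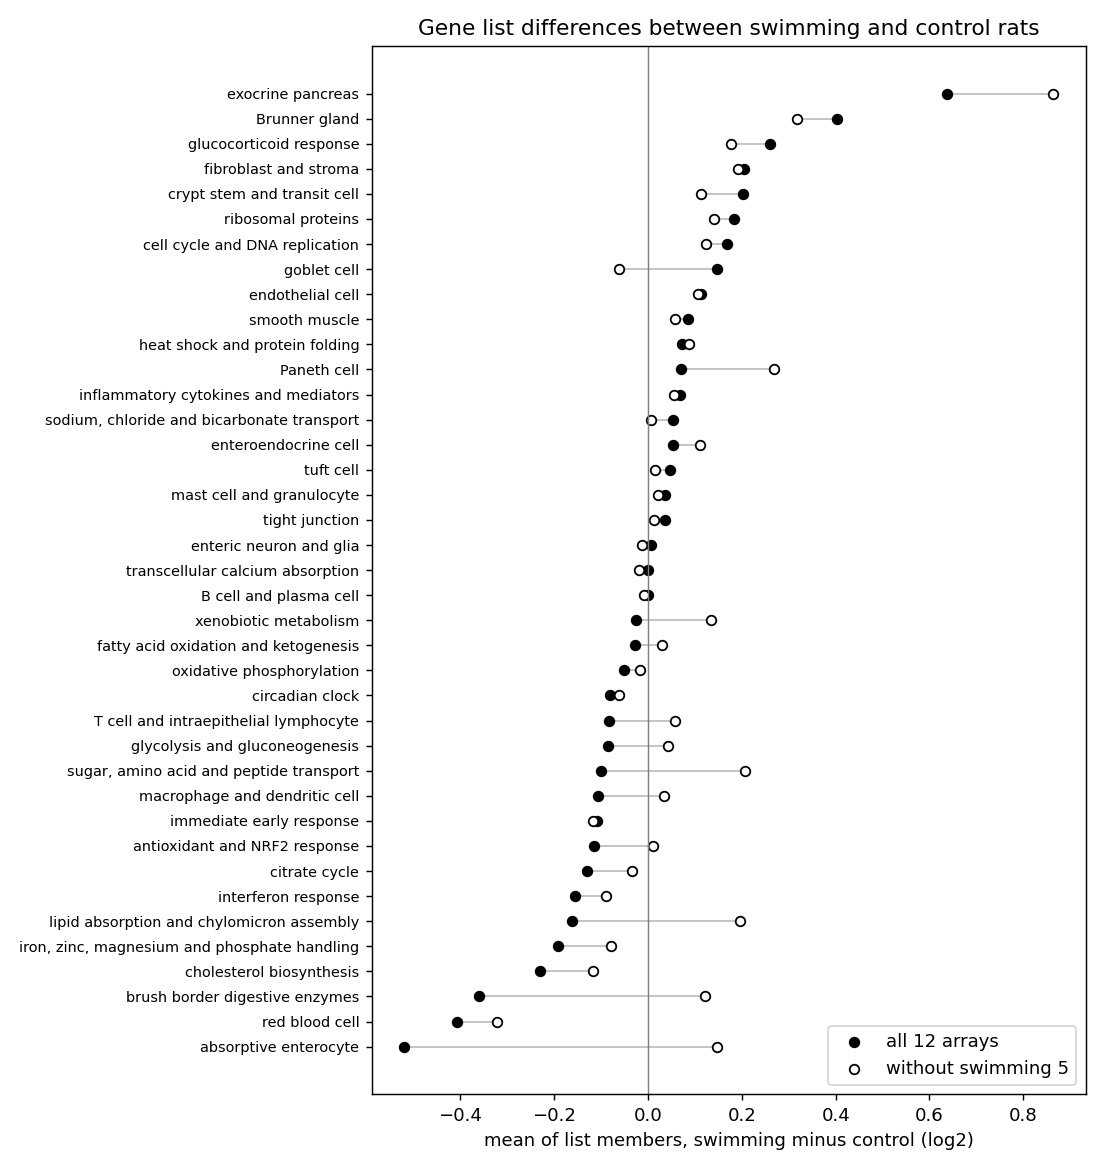
Mean log2 difference, swimming minus control, of the measured members of each of the 39 gene lists. Filled circles use all 12 arrays and open circles leave out swimming 5, with a line joining both values of a list. Absorptive enterocyte genes move from -0.52 to 0.15, and brush border enzymes from -0.36 to 0.12.

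Camera thus called 8 of 39 lists, and 13 without swimming 5, 14 without swimming 2 and 13 without swimming 3. In the restricted comparison it called 9, among them 6 of the 8. Beside the pancreas list these were ribosomal protein (0.16, adjusted p = 2.24e-05), cell cycle (0.14, 0.00637), interferon (-0.11, 0.00477), stroma (0.22, 0.00637) and red blood cell genes (-0.32, 0.0109). With an estimated correlation 0 of 39 were called in each of the full, swimming 5-free and restricted comparisons, and fry called 0 of 39. Unadjusted exact permutation tests of list means gave p = 0.00866 for red blood cell (0.0857 in the restricted comparison) and 0.0476 for interferon genes (0.171). For the other lists called on all arrays, exact p lay between 0.162 (ribosomal protein) and 0.457 (oxidative phosphorylation). With adjustment over the 39 lists the exact test called 0.

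Among the lists that were not called, the absorptive functions turned on the array labelled swimming 5. Sugar, amino acid and peptide transport genes differed by -0.099 on average with all arrays, where the median (0.036) and camera's direction were upward, and by 0.21 without swimming 5 (adjusted p = 0.000152 with the preset and 0.491 with an estimated correlation). Slc7a5, an amino acid exchanger, differed by 0.31. Lipid absorption and chylomicron genes differed by -0.16 with all arrays and by 0.20 without it (adjusted p = 0.0366, and adjusted p = 0.652 with an estimated correlation), and the ileal bile acid-binding protein gene Fabp6 by 0.62. Brush border enzymes differed by -0.36 and 0.12 (adjusted p = 0.0399, and adjusted p = 0.691 with an estimated correlation). In that list Tmprss15, enteropeptidase, differed by -1.45 with all arrays and by -0.26 without it. Xenobiotic metabolism genes differed by -0.026, where the median was 0.0085 and camera's direction upward, and by 0.13 without swimming 5 (adjusted p = 0.00770, and adjusted p = 0.548 with an estimated correlation), with Ugt1a1 at 0.50. The mean of this list turned to 0.058 under median scaling with all arrays. The 3 arrays with the highest pancreas means, control 3, swimming 2 and swimming 3, also had the highest means of these 4 lists. Control 3 and swimming 3 are near-identical and carry almost the same profile. The lipid list shares Pnlip and Clps with the pancreas list, so its agreement with that list may be partly built in. Lipid absorption averaged 10.98, 11.05 and 10.99 in them and 10.35 to 10.62 in the others apart from swimming 5, and xenobiotic metabolism 9.15, 9.16 and 9.16 against 8.74 to 8.98. Without swimming 2 the lipid list differed by -0.30 (adjusted p = 0.0354) and the brush border list by -0.49 (adjusted p = 0.0189). The brush border list was also called without swimming 3 (-0.49, adjusted p = 0.0275) and without control 4 (-0.42, adjusted p = 0.0298). With all arrays and an estimated correlation the adjusted p was 0.754 for the lipid and 0.742 for the brush border list.

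Glucocorticoid response genes averaged 0.26 higher in swimming rats and 0.18 without swimming 5. Of 22 measured, 14 read higher, the median was 0.073, and the list mean was higher in 6 of 6 swimming arrays. With all arrays the list was not called. Camera gave adjusted p = 0.0564 (adjusted p = 0.4997 with an estimated correlation) and the exact permutation test of the list mean p = 0.0303, or 0.394 adjusted over 39 lists, and p = 0.229 in the restricted comparison. With the preset correlation the list was called under median scaling (0.34, adjusted p = 0.0322), with the authors' values (0.33, adjusted p = 0.0310), and with eBayes trend and robust (adjusted p = 0.0437). It was also called without control 3 (0.28, adjusted p = 0.0490), swimming 1 (0.30, adjusted p = 0.0294) or swimming 6 (0.28, adjusted p = 0.0478). Fkbp5, a glucocorticoid-induced chaperone partner, read 9.70 ± 1.52 in control and 11.34 ± 0.93 in swimming rats (SD, n = 5 each), a difference of 1.99 (SE 0.63). Sult1a1 differed by 0.99 (SE 0.41; 0.60 without swimming 5) and Per1 by 0.62 (SE 0.31). Pck1 passed when adjusted over the list alone with all arrays, but no member did without swimming 5, where Pck1 differed by 1.40. Among circadian clock genes, Cry1 differed by -0.51 (SE 0.14), Bhlhe40 by -0.74 (SE 0.23), Nfil3 by -0.92 (SE 0.37) and Npas2 by -0.41 (SE 0.17), and Cry1 and Bhlhe40 passed when adjusted over the list alone. Without swimming 5 these 2 and Nfil3 (-1.14) passed in that way. As a list they averaged -0.081, with a median of 0.0059 and a mean of 0.024 under median scaling, and camera gave a downward direction with adjusted p = 0.303.

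Of the remaining functions, sodium, chloride and bicarbonate transport averaged 0.053 (0.0074 without swimming 5, with a median of -0.0028), with the chloride exchanger Slc26a3 at 0.68 (SE 0.22), the carbonic anhydrase Car4 at 1.31 (0.87 without swimming 5) and Slc4a7 at -0.99. Iron, zinc, magnesium and phosphate genes averaged -0.19 (adjusted p = 0.160), or -0.079 without swimming 5, with the iron importer Slc11a2 at -1.51 (-0.77 without swimming 5, where it passed when adjusted over the list alone) and the phosphate transporter Slc20a1 at 0.63. Fatty acid oxidation averaged -0.028, or 0.030 without swimming 5 (median -0.014) and 0.072 under median scaling, with the carnitine palmitoyltransferases Cpt1a at 0.45 (SE 0.14) and Cpt1b at -0.73 and the carnitine carrier Slc25a20 at -0.39. Heat shock and protein folding genes averaged 0.073 (adjusted p = 0.0564), with Herpud1 at 0.75 and Dnaja1 at -0.34. This list was called under median scaling (0.15, adjusted p = 0.0322), and without control 2 (0.10, adjusted p = 0.00733), control 3 (0.089, adjusted p = 0.0303) or swimming 2 (0.085, adjusted p = 0.0244), as well as with the authors' values (adjusted p = 0.0170), cyclic loess (adjusted p = 0.0484) and array weights (adjusted p = 0.0262). It had adjusted p = 0.551 with all arrays and an estimated correlation. Inflammatory mediators averaged 0.068, with Il1b at -0.44 and Lcn2 at 1.89 (SE 0.80). Lcn2 read 11.62 and 11.53 in the near-identical swimming 4 and swimming 6, 9.79 in swimming 5 and 9.20 in swimming 1. It read 6.89 in swimming 2 and 6.74 in swimming 3, and between 6.84 and 8.21 in the controls. Immediate early genes averaged -0.11 (adjusted p = 0.0860), with Ier5 at -0.53, and -0.12 without swimming 5 (adjusted p = 0.0363, and adjusted p = 0.548 with an estimated correlation) and -0.16 without control 2 (adjusted p = 0.0110). The citrate cycle averaged -0.13 (adjusted p = 0.0583), or -0.034 without swimming 5 (adjusted p = 0.668). With the preset correlation it was called with the authors' values (-0.15, adjusted p = 0.0152), and without control 5 (-0.18, adjusted p = 0.00105), swimming 2 (-0.17, adjusted p = 0.0189) or swimming 3 (-0.18, adjusted p = 0.00636), and had adjusted p = 0.708 with all arrays and an estimated correlation. Glycolysis and gluconeogenesis averaged -0.085 (0.042 without swimming 5, median -0.0069) and antioxidant genes -0.11 (0.012 without it, median -0.0080). In the glycolysis and gluconeogenesis list Pck1 alone passed with all arrays when adjusted over the list alone, and no member without swimming 5.

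Among the remaining cell types, absorptive enterocyte genes averaged -0.52 with all arrays and 0.15 without swimming 5, with Alpi at -1.47 and 0.0051 and Fabp2, an enterocyte fatty acid-binding protein, at -0.45 and -0.12. Brunner gland genes averaged 0.40 (adjusted p = 0.0564; exact permutation p = 0.0281, or 0.394 adjusted over 39 lists and 0.171 in the restricted comparison), with Tff2, a trefoil peptide of these glands, at 1.46 (SE 0.52). The list averaged 0.32 without swimming 5 (adjusted p = 0.0363, and adjusted p = 0.491 with an estimated correlation) and 0.49 without swimming 2 (adjusted p = 0.0238). Crypt stem and transit cell genes averaged 0.20 (0.11 without swimming 5), and Ephb2, a receptor of crypt cells, at 0.46 (SE 0.13), passed when adjusted over the list alone. Enteroendocrine genes averaged 0.053, and 0.11 without swimming 5 (adjusted p = 0.0399, and adjusted p = 0.615 with an estimated correlation), with Chga at 0.24 and the secretin gene Sct at -0.68 (-0.40 without swimming 5). Goblet cell genes averaged 0.15 with all arrays and -0.061 without swimming 5. Differences were 0.070 for Paneth cell (0.27 without swimming 5), 0.047 for tuft cell (0.016 without it), 0.085 for smooth muscle and 0.11 for endothelial cell genes. They were -0.083 for T cell (0.058 without swimming 5), -0.11 for macrophage and dendritic cell (0.034 without it, median -0.0068), 0.037 for mast cell and granulocyte (0.022 without it) and 0.0057 for enteric neuron and glia genes (-0.012 without it, median 0.026). B cell and plasma cell genes averaged -0.00052, with a median of 0.067, an upward direction in camera and means of 0.045 under median scaling and 0.0048 under cyclic loess, and Prdm1, the plasma cell regulator Blimp-1, differed by -0.59 (SE 0.19). With all arrays the preset adjusted p lay between 0.0564 and 0.783 over these cell types. The smooth muscle means of swimming 1 and control 2, 7.69 each, stood above those of the other arrays (7.08 to 7.50). The enterocyte list was called without swimming 2 (-0.67, adjusted p = 0.0410) or swimming 3 (-0.67, adjusted p = 0.0417), and the endothelial list without control 2 (0.16, adjusted p = 0.00635), swimming 2 (0.13, adjusted p = 0.0250) or swimming 3 (0.14, adjusted p = 0.0417). The T cell list was called without swimming 3 (-0.17, adjusted p = 0.0136). With all arrays and an estimated correlation the adjusted p was 0.742 for the enterocyte, 0.599 for the endothelial and 0.742 for the T cell list. None of the 39 lists was called with an estimated correlation on all arrays.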

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

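The tests that weigh explanations for the 2 patterns here were chosen after the results were seen, except the count of called lists over other splits. Within groups of 5 samples, 30 of 252 values examined had 1 sample far from the rest, where chance gives about 1 in 20, and 22 of the 30 belonged to the array labelled swimming 5. Values below are that sample minus the median of the others of its group, in log2.

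In swimming 5 the list means lay apart for absorptive enterocyte (-4.02), brush border enzymes (-2.91), lipid absorption (-2.25), sugar, amino acid and peptide transport (-1.84), xenobiotic metabolism (-1.01), macrophage and dendritic cell (-0.82), glycolysis and gluconeogenesis (-0.80), antioxidant (-0.79) and iron, zinc, magnesium and phosphate genes (-0.70). Its single genes apart were Alpi (-8.87), Tmprss15 (-7.48), Slc11a2 (-4.51), Fabp2 (-2.01), Prlr (-1.96), Bhlhe40 (-1.28), Cpt1b (-0.41), Akr1c2 (-0.35), Cldn3 (0.61), Pmvk (0.82), Cyp24a1 (1.54), Atp2a3 (2.23) and Car4 (2.73). Alpi and Tmprss15 read 5.998 and 5.84 in swimming 5, in the range of dim probes, so their differences may understate the change in RNA. Control 3 lay apart in the exocrine pancreas list (2.27), its member Cel (2.09) and the lipid absorption list (0.57), which holds pancreatic lipase. Control 2 lay apart in endothelial (0.29) and inflammatory (0.17) genes. Swimming 3 lay apart in Rpl23a (-0.39) and Taldo1 (0.23), and swimming 1 in Col1a2 (1.34).

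The array labelled swimming 5 lost proximal small intestine genes and carried large intestine genes. A dim array is argued against, since its upper-quartile raw intensity, 237, was the highest of the 12. Over the 7 large intestine markers that set it apart, the other 5 swimming arrays differed from the controls by a median of -0.078 log2. These markers were kept because swimming 5 exceeded every other array, which selects against markers raised in the whole group. The value therefore cannot decide on an effect of swimming shared by the group. Tissue of the large intestine under a duodenum label is a candidate explanation. By more than 1 log2, 15 of 19 proximal markers lay below all other arrays and 7 of 13 large intestine markers above them. The loss of proximal markers alone would not tell the ileum from the large intestine. Of 6 measured ileum markers, 1 lay above all other arrays by more than 1 log2 (Nr1h4) and 1 below (Slc51a). Whether the sample, the dissection or the label was exchanged stays open, and a response in this rat alone was not tested.

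Near-identical arrays may be repeat arrays of one RNA. The bright spread was at most 0.949 times the dim spread in the 3 pairs and at least 1.35 times in the other 52, and 0 of 22 probes that switch between low and high levels differed within the 3 pairs. These 22 were picked from the same arrays, without probes in which a single array stood alone, so that 0 is partly built in. Separate rats that are alike cannot be told apart from this, because the labels give no litter or extraction, although every other pair differed by more than 1 log2 in at least 51 bright probes. For control 3 and swimming 3 a repeat array would mean that 1 of the labels is wrong, and which of them was not tested.

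Other splits of the 12 arrays into 6 and 6 do not set the real groups apart. Of 100 splits drawn from 462, the real one included, 68 had at least as many lists called by camera as the real 8, the highest of the others being 19, so chance is not excluded for that count. The splits treat near-identical arrays as separate and all 12 arrays as exchangeable. For probes, all 100 splits trivially reach the real count of 0. Of the 100, 2 called any probe, and the highest was 24.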

How the results depend on the processing

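The 26 probe fits, the main one included, called 0 probes each. The counts at an unadjusted p under 0.05 lay between 760 and 1658 when single arrays were left out, the highest without control 2. They were 556 with the authors' values, 630 with near-identical pairs averaged and 588 with swimming 5 left out as well. In the authors' values nearly all values below each array's median sat at the floor. Dim probes could hardly differ there, which limits that count and the comparison of list calls with the main fit. The settings that average near-identical pairs or leave out several arrays, and the exact permutation of all list means, were chosen after seeing the data. With the replicate number as a block, limma called 0 probes (1052 unadjusted), camera 10 lists, among them glucocorticoid response (adjusted p = 0.0315) and citrate cycle (adjusted p = 0.0141), and the calcium list kept its difference of -0.00015 (exact paired p = 1). Same-numbered arrays deviated together with r of 0.73 for number 3, 0.25 for 6 and 0.15 for 4, and between -0.025 and 0.00086 for the others, and control 3 and control 6 alone correlated best with their own number, so the replicate block pairs nothing that the labels state. The 8 called lists became 14 with the authors' processed values, and 0 with an estimated correlation, with fry and with exact permutation (chosen after seeing the data). Leaving out single arrays gave 6 to 14 lists, with 13 without swimming 5 and 13 without swimming 3, and other settings gave 7 to 12. A single list cannot pass the exact test over 39 lists, so its count of 0 was nearly fixed. Calls also appeared for immediate early genes with the authors' values (adjusted p = 0.0195) and array weights (0.0262), Brunner gland with eBayes trend (0.0437), array weights (0.0287) and averaged pairs without swimming 5 (0.0388), endothelial genes with offset 16 (0.0486), eBayes trend (0.0437) and array weights (0.0262), and brush border (0.0310, 0.0296) and enterocyte genes (0.0152, 0.0497) with the authors' values and averaged pairs. The cause was not tested.

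The calcium list mean turned sign with median scaling (0.044), cyclic loess (0.0050) and averaged pairs (0.0065), and lay between -0.020 and 0.024 when single arrays were left out, with exact p of at least 0.597. The tight junction mean was -0.00028 in the restricted comparison and otherwise above 0, between 0.012 and 0.050 when single arrays were left out. The lipid absorption list turned to 0.20 without swimming 5, to 0.24 with pairs averaged as well and to 0.29 in the restricted comparison, and the brush border list to 0.12 without swimming 5. Without swimming 2 they lay at -0.30 and -0.49. Over the 39 lists and all settings, 988 of 1090 values kept their side of the threshold, 46 lost and 52 gained a call, and 4 were called in the opposite direction. None of 4401 values of 176 named genes gained a call. Over all settings the median of all probes lay between -0.0058 and 0.012 log2. Chip as a block was not run, because the files give no chips. Without detection p-values, dim probes limit what can be read from the weakly expressed calcium genes.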

Other observations

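The tests here were chosen after the glucocorticoid and clock results were seen. Of 5 clock genes of the phase of Bmal1, 4 read lower in swimming rats, with Nfil3 at -0.92 (SE 0.37), Cry1 at -0.51 (SE 0.14), Npas2 at -0.41 (SE 0.17) and Bmal1 at -0.26 (SE 0.24), while Clock differed by 0.023. Genes of the opposite phase read higher or alike, with Per2 at 0.47 (SE 0.57), Nr1d1 at 0.18 (SE 0.33), Tef at 0.14 (SE 0.13), Per3 at 0.027 and Dbp at 0.0059. None passed over all probes. Bhlhe40, which like Per2 is driven by the clock from E-box elements, read lower (-0.74, SE 0.23) and is in neither set, which goes against a common direction of such genes. Over all 15 measured clock genes 8 read higher and 7 lower, with a median of 0.0059.

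The mean of the glucocorticoid response list was higher in swimming rats, led by Fkbp5 and Pck1, with 14 of 22 members higher and a median of 0.073, and although the list was not called, the difference may have more than 1 source. The array labelled swimming 5 alone neither carries nor loses the pattern clearly, since the list difference was 0.178 without it (exact permutation p = 0.0584), 0.26 with it (p = 0.0303) and 0.18 in the restricted comparison (p = 0.229), which alone leaves no near-identical arrays counted as separate. Another time of day at dissection, a hypothesis, was tested through the 5 genes of the Per2 phase less the 5 of the Bmal1 phase, leaving out Bhlhe40, 3 other measured clock genes and Per1, which stands in both lists. That difference was 0.580 log2 (exact permutation p = 0.113), 0.704 without swimming 5 (p = 0.0736) and 0.797 in the restricted comparison (p = 0.0571). The smallest possible p in the restricted comparison is 0.0286. The test leaves the hypothesis open. The labels give no hour of dissection, and a response to the exercise or its handling stays open and untested.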
